A study of Mus musculus with 3 samples.

How the data were processed

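DNase-seq libraries of MEL cells, a mouse erythroleukemia line arrested early in the red cell lineage, were analysed. DNase I cuts chromatin where DNA is accessible, and sequenced cut ends pile up at promoters, enhancers and other regulatory sites. The 3 libraries belonged to 2 biological replicates of 1 condition, per the labels. Biological replicate 1 had 2 libraries, carrying the technical replicate numbers 1 and 3, and biological replicate 2 had 1 library.

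The authors deposited called regions. Per the deposited notes, the replicate 1 peaks and hotspots were called on an alignment merged from both of its libraries, and the replicate 2 regions on the alignment of its own library. Each biological replicate therefore had 1 list of peaks and 1 list of hotspots, and the spread between technical replicates could not be measured. The build was mm10, per the labels. The aligner, the peak caller and the read numbers were not given in the sources used here, so the depth is unknown. Merging 2 libraries can change how many weak sites pass a caller's limit, so list sizes are not comparable as biological quantities.

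Each deposited peak carries a score in the signal column of its format. Scores were whole numbers from 1 to 150 and never exceeded the peak width of 150 bp, so they are compressed at the top. What the score counts was not given in the sources used here. It is the authors' value and was used to describe, rank and filter peaks within a list. The deposited hotspots carry a −log10 q-value by the convention of their format, with a lowest value of 1.30 and a cap at 100; in this work hotspots served only as positions.

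Exact repeats of a peak were dropped, which removed 67 lines from the replicate 1 list and 7 from the replicate 2 list. Positions were compared with the GRCm38 reference sequence and the GENCODE M21 basic annotation, the same build as mm10. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A peak counted as found in the other list when at least 1 bp overlapped. Chance overlap came from 20 circular shifts of the other list along each chromosome. A promoter peak was a peak centred within 1000 bp of the start of a protein-coding transcript. Remaining peak centres were assigned to exons, introns or intergenic sequence, in that order.

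The 17 gene lists and 18 consensus motifs were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 325 listed genes, 322 were found as protein-coding genes in the annotation. Each list's number of genes with a promoter peak was set beside 10000 random lists of the same size, drawn from genes in the same of 5 classes of promoter CpG content within 500 bp of the start. Percentiles describe these lists of peaks and are not p-values, since genes are not replicates. Motif matches on either strand were counted in the 150 bp around the peak centre and in windows 1000 bp to either side that overlapped no peak of either list. The share of 32-bp words occurring once in the genome was computed for each listed promoter, because reads from repeated sequence can be lost.

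The rule named up to 4 genes per list with the highest promoter score in the replicate 2 list, any member of the erythroid factor, heme and globin lists, and genes nearest to the 10 highest-scoring peaks of each list. In the replicate 1 list 583 peaks outside the mitochondrial genome and unplaced contigs tied at 150, so its 10 highest could not be ranked and were not used. Genes named as lacking a promoter peak in other lists were chosen after their values were seen.

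With 1 list per biological replicate, no test between samples and no p-value was possible. Wilson 95% intervals on shares, and intervals on ratios from the counts, cover counting error over peaks only. Code was tested on simulated data. All 800 simulated peaks were called correctly under each of 3 overlap rules, all 720 planted motif instances were found, and 15 of 200 random lists fell outside the 5th to 95th percentile range. Alternatives tried were other overlap rules, the higher-scoring 50% of each list, lists cut to equal length, autosomes only, hotspots in place of peaks, other promoter widths, all annotated genes, other motif windows and backgrounds, and each biological replicate alone.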

Results

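Accessible chromatin was mapped by DNase-seq in MEL cells, a mouse erythroleukemia line used as a model of red cell precursors. The merged libraries of biological replicate 1 gave 281600 peaks, covering 41.2 Mb, and the library of biological replicate 2 gave 89046 peaks, covering 13.2 Mb. The median deposited score was 73 in the replicate 1 list and 32 in the replicate 2 list. There were 224643 hotspots in replicate 1 and 82150 in replicate 2. There is no replicate list within either biological replicate, and the read depth behind the lists is unknown.

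The first comparison asked how far the biological replicates shared their accessible sites. Of the replicate 2 peaks, 94.6% (Wilson 95% interval 94.5 to 94.8%) were overlapped by a replicate 1 peak, against a mean of 3.08% after circular shifts. In the other direction 30.2% of replicate 1 peaks (29.99 to 30.33%) were overlapped, against 1.00% after shifts. The replicate 1 share depended on score, rising from 1.22% among the lowest 10% of scores to 96.2% among the highest. With both lists limited to the same number of highest-scoring peaks, 75% of the replicate 2 peaks and 74.3% of the replicate 1 peaks were shared, so both shares moved with list length. Across 84275 overlapping pairs, scores were correlated with a Spearman rho of 0.92 and a Pearson r of 0.81. This is across peaks, which are not independent replicates. Replicate 1 had the higher score in 84274 pairs, with medians of 121 against 32. The pairs of scores given below therefore do not compare accessibility between the replicates.

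**Figure D1:**
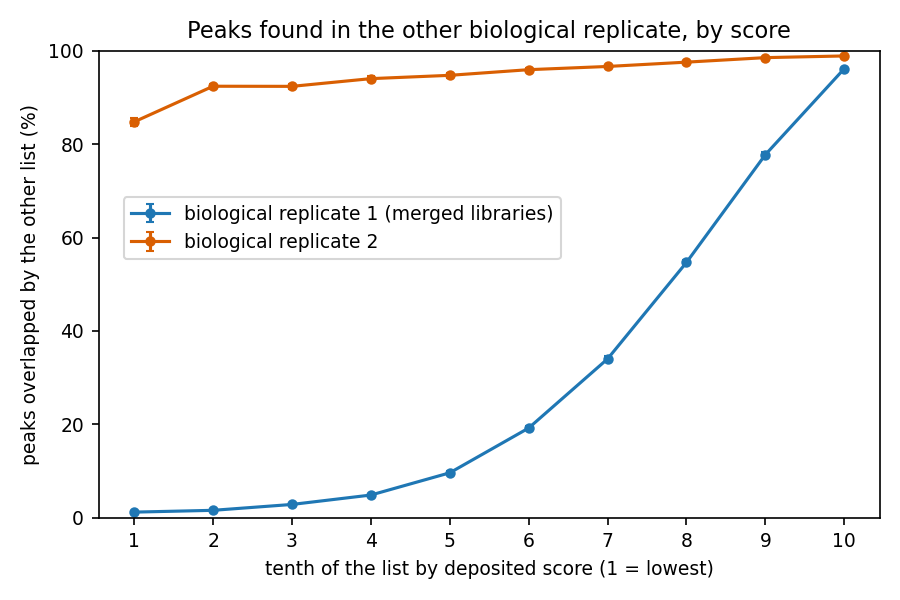
Share of peaks overlapped by the other list (vertical axis, percent) for each 10% of a list by deposited score (horizontal axis), with Wilson 95% intervals. The replicate 1 share climbs from 1.22% to 96.2%, while the replicate 2 share runs from 84.8% to 98.9%.

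Peaks were concentrated at gene starts. Promoters held 21.2% of replicate 2 peaks (20.9 to 21.5%) and 12.3% of replicate 1 peaks (12.2 to 12.4%), against 2.01% and 2.07% for shifted peaks. Replicate 1 peaks overlapped by replicate 2 lay at promoters in 20.2% of cases and those found in replicate 1 alone in 8.89%. Replicate 2 showed the reverse, with 20.4% for overlapped peaks and 36.4% for those found in replicate 2 alone. Most of the latter lay near a replicate 1 peak without touching it. Of 4771 replicate 2 peaks without overlap, 726 lay over 500 bp from any replicate 1 peak. The replicate 1 share over all peaks moved with the choice of peaks and width: it was 25.9% at equal list length, above the replicate 2 share, 20.3% for the higher-scoring 50% and 20.9% within 2500 bp. Intergenic sequence held 39.4% of replicate 2 peaks against 59.3% of shifted peaks, and introns held 36.8% against 36.2%. A promoter peak was present for 12732 of 21851 protein-coding genes in replicate 1, for 10804 in replicate 2 and for 10794 in both.

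Most listed erythroid factor, heme and red cell membrane genes had promoter peaks, while globin genes had them in some cases. Random lists were matched on promoter CpG content only, and housekeeping and cell cycle lists were also high. High counts are therefore not particular to red cell genes. All 20 erythroid transcription factors had a promoter peak in replicate 1 and 19 had one in replicate 2. There the central 95% of random lists of matched CpG content gave 9 to 16. Gata1, the master regulator of red cell development, scored 141 in replicate 1 and 71 in replicate 2, the latter at chromosome X 7967936 to 7968085, inside the annotated gene (ENSMUSG00000031162.14). Klf1, which activates adult beta-globin, scored 140 and 84, and Tal1 scored 143 and 46. The highest replicate 2 scores of the list belonged to the corepressor gene Cbfa2t3 (147 and 102), Klf13 (144 and 95), Foxo3 (145 and 92) and Nfe2l2 (149 and 88). Sox6 scored 41 in replicate 1 and had no promoter peak in replicate 2.

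Heme synthesis and iron uptake genes had promoter peaks in 19 of 20 cases in replicate 1 and in 18 of 20 in replicate 2, where random lists gave 10 to 17. Ppox, an enzyme of the heme pathway, scored 150 and 105, Glrx5, which acts in iron-sulfur cluster assembly, 149 and 105, the ferritin light chain gene Ftl1 147 and 94, and the ferrireductase gene Steap3 147 and 91. The replicate 2 peak at Glrx5 was closer to the start of Snhg10. Alas2, the erythroid enzyme that starts heme synthesis, scored 85 in replicate 1 and had no promoter peak in replicate 2. Outside the promoter window, a peak inside the gene scored 147 in replicate 1, 2536 bp from its start. The replicate 2 list had a peak of 94 there, at 2516 bp. Slc25a37, the mitochondrial iron importer, had no promoter peak in either list, and 0% of the 32-bp words of its promoter were unique in the reference, so a peak there may not have been detectable.

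Red cell membrane and surface genes had promoter peaks in 19 of 20 cases in replicate 1 and in 15 of 20 in replicate 2, where random lists gave 5 to 12. Epor, the erythropoietin receptor, led with 149 and 106, followed by Epb41 (141 and 100), Icam4 (148 and 82) and Kel (144 and 80). Slc4a1, the anion exchanger of mature red cells, had no promoter peak in either list, and its promoter was 98.0% unique. Rhd, Tmod1, Dmtn and Car2 had one in replicate 1 alone.

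The globin genes, whose expression MEL cells raise on induced differentiation, had promoter peaks in some cases. Of 10 annotated globin genes, 6 had one in replicate 1 and 3 in replicate 2, where random lists gave 0 to 6 and 0 to 4. Hbb-bt scored 128 and 40, Hbq1a 135 and 32, and Hbq1b 96 and 20. Hbb-bs, Hbb-bh2 (99) and Hba-a1 (71) had promoter peaks in replicate 1 alone, and Hba-a2, Hba-x, Hbb-y and Hbb-bh1 had none. Duplication limits some of these values: the unique share was 25.3% for the Hba-a1 promoter, 19.1% for Hba-a2, 57.3% for Hbb-bt and 56.2% for Hbb-bs. It was 96.5% for Hba-x, 100% for Hbb-y and 98.9% for Hbb-bh1, so this limit is small for those. Outside the genes, the beta-globin locus had strong peaks upstream of Hbb-y, where the locus control region lies. The replicate 2 list had a peak of score 88 at chromosome 7 103861036 to 103861185, and others of 74 at 103859196 to 103859345 and 69 at 103870796 to 103870945. At the alpha-globin locus, its highest peak within 50 kb of Hba-a1 scored 68 at chromosome 11 32265256 to 32265405, inside Nprl3, the neighbouring gene that holds alpha-globin enhancers.

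**Figure D2:**
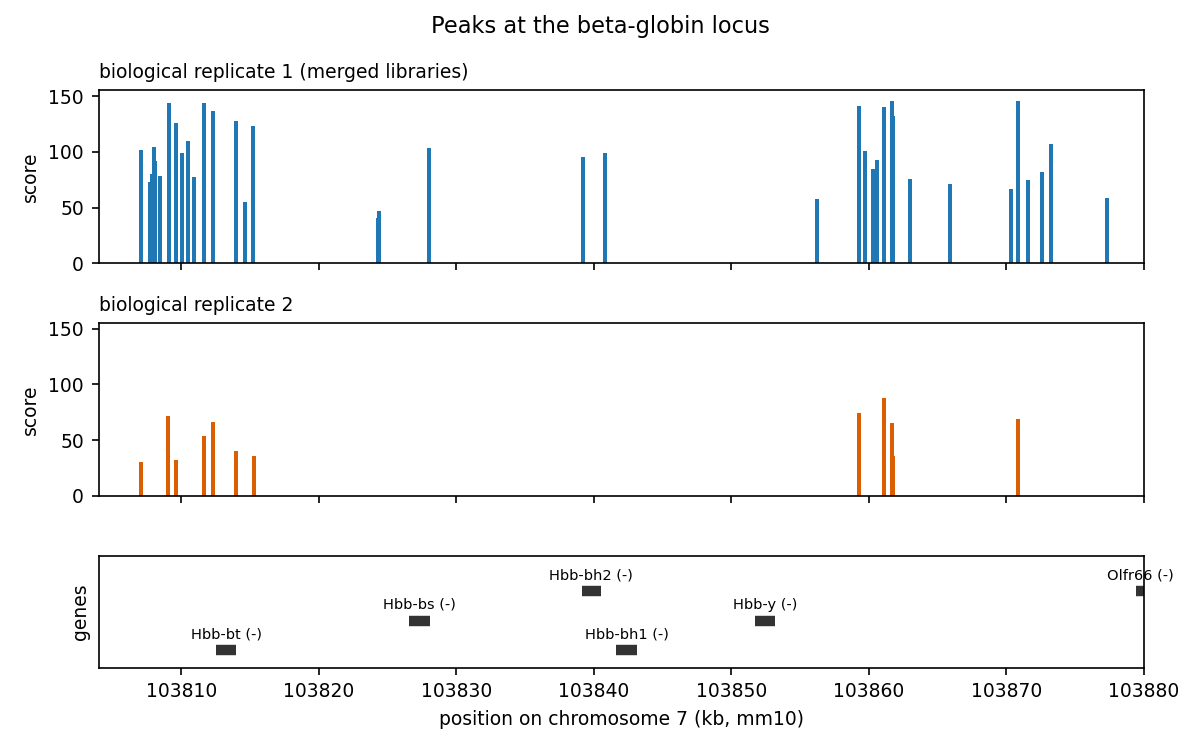
Deposited peak scores (vertical axes) along the beta-globin locus on chromosome 7 (horizontal axis, kb, mm10) for both lists, with protein-coding genes as boxes and their strand in brackets. Replicate 2 has no peak between 103815345 and 103859196, which spans Hbb-bs to Hbb-y, and peaks of up to 88 upstream of Hbb-y.

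Promoters of other blood lineages were also accessible in part. Myeloid markers had promoter peaks in 15 of 20 cases in replicate 1 and in 10 in replicate 2, where random lists gave 0 to 6. Cd68 scored 150 and 109, Fcgr1 150 and 104, Csf3r 142 and 66, and Cebpe 139 and 59. Fcgr1 lies in a stretch of chromosome 3 with high scores, described under other observations, so its score need not be particular to this promoter. Megakaryocyte markers had 11 of 16 in replicate 1 and 7 in replicate 2, the upper end of the 1 to 7 given by random lists. The platelet glycoprotein gene Gp1ba scored 146 and 93, Itga2b 146 and 79, Pf4 141 and 73, and Gp5 143 and 63. Lymphoid markers had 12 of 20 in replicate 1, above the 3 to 11 of random lists, and 4 in replicate 2, inside the 1 to 8 of random lists. Those 4 were Cd5, Il7r, Ebf1 and Cd22, which scored 53, 44, 35 and 27.

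Blood stem and progenitor genes stood inside the random range, with 13 of 20 in each list. Spi1, which encodes the ETS factor PU.1, scored 148 and 123, Myc 145 and 86, Runx1 142 and 73, and Meis1 145 and 65. Kit, Erg, Hoxa9, Cd34, Ly6a, Mecom and Flt3 had no promoter peak in either list; at most 53.7% of the Ly6a promoter was unique, so a peak there may not have been detectable. The Spi1 promoter score came from a peak in the first exon of its longest transcript, at chromosome 2 91096816 to 91096965 in replicate 2. As described under other observations, DNA copies of the spliced transcript were not excluded as a source of Spi1 exon peaks. The Spi1 score therefore need not reflect an accessible promoter. In each list a hotspot also crossed the start of that exon, from 321 bp upstream in replicate 1 and 231 bp upstream in replicate 2. The replicate 1 hotspot ran 2012 bp past the exon's end, and the replicate 2 hotspot ended at 91096148, before the scored peak. Copies of that transcript hold no sequence outside the exon there, so these hotspots argue against copies as the only source of signal at the start. Peaks also lay in exons 2, 3, 4 and 5 of Spi1, with replicate 2 scores of 78, 135, 137 and 145. The last was the second highest of that list outside the mitochondrial genome and unplaced contigs.

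**Figure D3:**
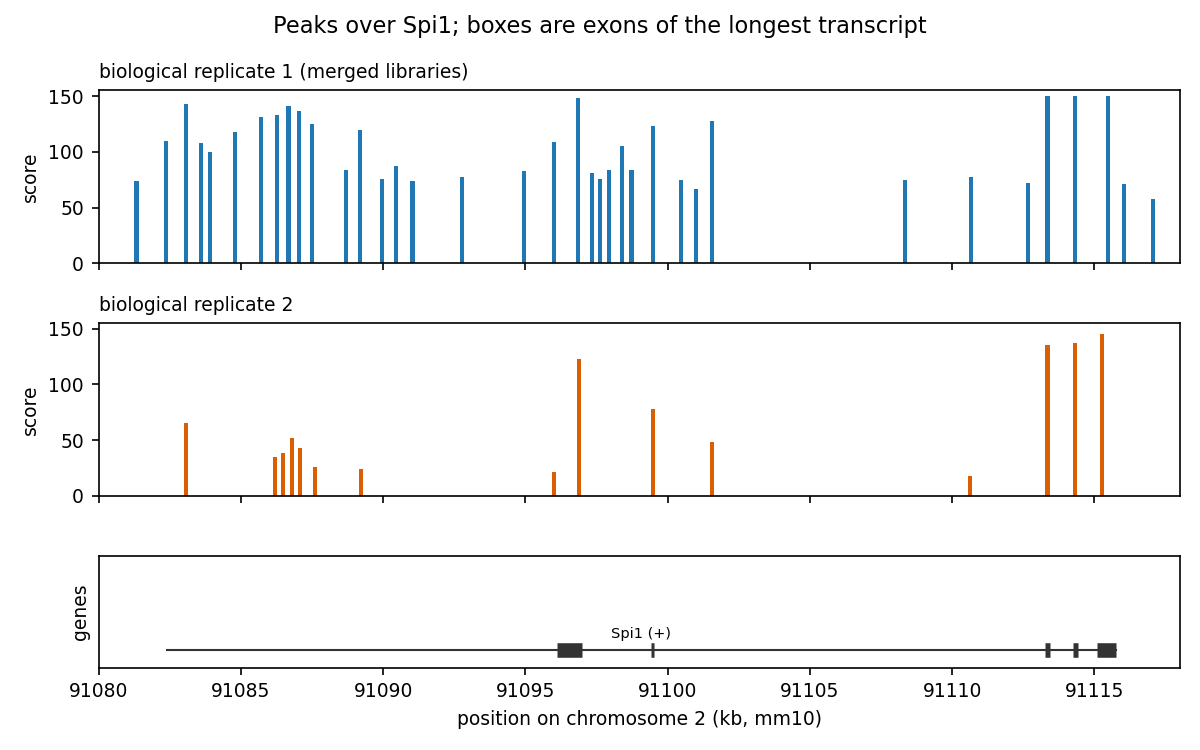
Deposited peak scores (vertical axes) along Spi1 on chromosome 2 (horizontal axis, kb, mm10) for both lists, with exons of the longest transcript as boxes. The peaks in exons 3, 4 and 5 score 150 in replicate 1 and 135, 137 and 145 in replicate 2. DNA copies of the spliced transcript were not excluded as their source.

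Markers of unrelated tissues had few promoter peaks. In replicate 2, pluripotency genes had 1 of 20 (Gdf3, score 38), epithelial and skin markers 1 of 20 (Cldn3, 49), neuron markers 1 of 20 (Syn1, 26) and hepatocyte markers 1 of 20 (Alb, 12). Random lists gave 6 to 14, 6 to 13, 8 to 16 and 1 to 7 in the same order, so the hepatocyte count lay inside its range. Fibroblast and matrix genes had 3 of 20 (Thy1, 54; Col1a1, 35; Pdgfra, 34) against 4 to 12, and muscle markers 2 of 20 (Tnni2, 82; Ryr1, 48) against 2 to 9. In replicate 1, neuron markers numbered 6, below their random range of 9 to 17, while muscle markers (6) and fibroblast genes (7) lay inside theirs.

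Housekeeping genes and genes of the cell cycle and its control formed the opposite end. All 20 housekeeping genes, all 20 cell cycle and replication genes and all 16 tumour suppressor and cell cycle inhibitor genes had promoter peaks in both lists. Random lists gave 12 to 19, 13 to 19 and 10 to 16 in replicate 1, and 11 to 18, 11 to 19 and 9 to 15 in replicate 2. In replicate 1 the upper limit for tumour suppressor genes was the full list of 16, so no count could lie above it. Of the listed genes, Ccnd3, a D-type cyclin, scored 150 and 110, Mcm3 149 and 106, Stk11 148 and 118, Vcp 148 and 96, and Trp53 144 and 82. Atm (149 and 109), Brca1 (149 and 98), Mcm7 (149 and 95) and Rps18 (147 and 91) had strongest peaks that lay closer to the start of a neighbouring gene.

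**Figure D4:**
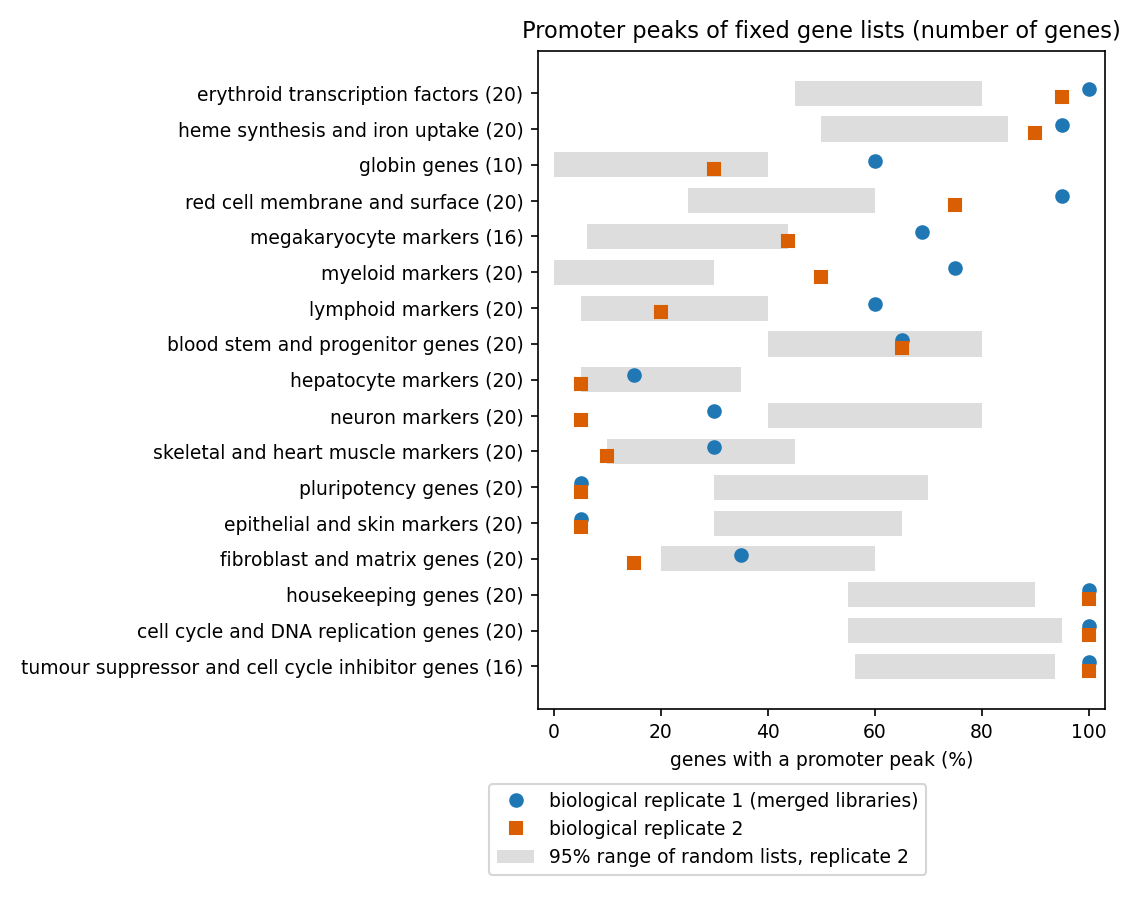
Share of each fixed list's genes with a promoter peak (horizontal axis, percent) in replicate 1 (circles) and replicate 2 (squares), with the 95% range of random lists for replicate 2 as grey bars. Erythroid factors (95%) lie above their bar in replicate 2, and pluripotency genes (5%) below theirs.

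Markers of unrelated tissues had fewer peaks in and around them than erythroid genes, while housekeeping genes had about as many. The 70 genes of the 4 erythroid lists had a median of 44 replicate 1 peaks and 14 replicate 2 peaks from 50 kb upstream to 50 kb downstream, promoters and gene bodies included. The 120 genes of the 6 lists of other tissues had medians of 21 and 7, housekeeping genes 49.5 and 14, and tumour suppressor and cell cycle inhibitor genes 40.5 and 14. No test of these differences was run. At equal list length the replicate 1 medians were 20 for the erythroid lists and 5 for other tissues, and within 10 kb they were also 20 and 5, with 6 and 1 in replicate 2. Erythroid transcription factors had the highest list median, 57 in replicate 1 and 16.5 in replicate 2, and pluripotency genes had the lowest in replicate 2, at 3.5. Globin genes of a cluster share the same peaks, so their counts are not independent.

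Peaks were rich in consensus sites of blood and general factors. GATA sites occurred in 17.1% of replicate 2 peaks and 8.57% of flanking windows, a ratio of 1.99 (1.95 to 2.04). The replicate 1 ratio was 1.59 (1.57 to 1.61). CTCF sites occurred in 4.74% of replicate 2 peaks and 0.034% of flanks, a ratio of 138.3 (104.4 to 183.2), and the replicate 1 ratio was 58.3 (50.5 to 67.3). The NF-E2 site, bound by an erythroid leucine zipper factor, gave 12.4 (9.62 to 16.1) in replicate 2 and 11.1 (9.59 to 12.8) in replicate 1. Every match to it also contains the shorter AP-1 site, which the motif list classed as general. AP-1 sites gave 3.06 in replicate 2 and 2.73 in replicate 1, so the NF-E2 ratio does not single out 1 factor. KLF sites gave 3.14 (3.01 to 3.28) and RUNX sites 2.503 (2.38 to 2.64) in replicate 2. The PU.1 site lay in 318 of 88878 replicate 2 peaks and 2 of 142941 flanks. Of sites that the motif list had classed under other tissues, HNF4 gave 0.87 (0.71 to 1.05) and MEF2 1.17 (1.00 to 1.36). The RFX X-box gave 3.22 (1.56 to 6.63), and REST sites lay in 76 replicate 2 peaks and no flank. Whether the factors of these sites are present in MEL cells was not measured, so the class does not mark them as foreign to the line. Ratios of long and short sites are not comparable, since a long site rarely occurs by chance. The CTCF ratio moved to 271.2 in replicate 2 and 92.9 in replicate 1 within 75 bp of sequence, and to 80.6 and 90.3 in the higher-scoring 50%. With GC-matched flanks the replicate 2 ratio fell to 2.08 for KLF and rose to 2.03 for MEF2.

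**Figure D5:**
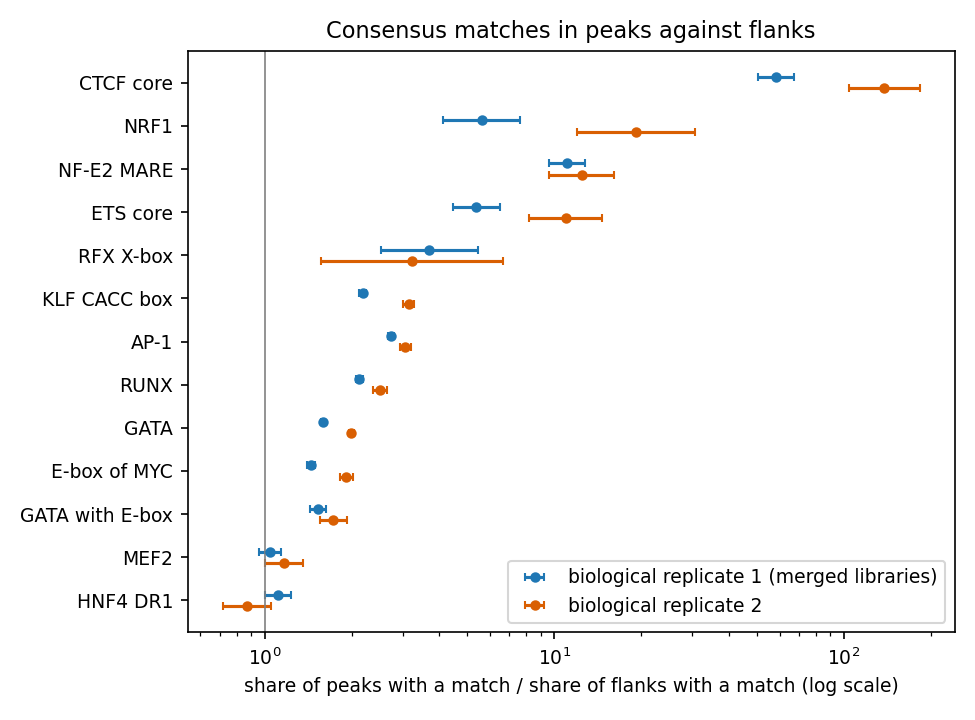
Ratio of the share of peaks with a consensus match to the share of flanking windows with one (horizontal axis, log scale), with 95% intervals from the counts, for both lists and motifs with at least 10 matching flanks in each list. CTCF lies highest, at 138.3 in replicate 2, and HNF4 lowest, at 0.87.

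Sites found in replicate 1 alone gave lower ratios for several motifs. GATA gave 1.44 (1.41 to 1.46) there against 1.95 (1.91 to 2.00) in replicate 1 peaks overlapped by replicate 2. CTCF gave 30.6 (26.0 to 36.1) against 160.6 (117.6 to 219.2), and NRF1, a site of CpG-rich promoters, 1.29 (0.78 to 2.12) against 13.8 (8.45 to 22.4). The NF-E2 intervals overlapped, at 10.3 (8.66 to 12.2) against 13.0 (9.95 to 16.9). Ratios were higher in replicate 1 alone for the RFX X-box, 4.38 (2.73 to 7.002) against 2.49 (1.24 to 5.01), and for HNF4, 1.20 (1.06 to 1.36) against 0.92 (0.76 to 1.11), with overlapping intervals. The PU.1 site lay in 0.118% of replicate 1 peaks found there alone and 0.341% of overlapped peaks, with too few matching flanks for a ratio. Peaks found in replicate 1 alone had a median score of 58, against 121 for overlapped peaks. They also lay at promoters less often, in 8.89% against 20.2% of cases. The ratios in this comparison were not matched on score or location.

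Every peak touched a hotspot of its own list and every hotspot held a peak, with 1.25 peaks per hotspot in replicate 1 and 1.08 in replicate 2. Whole peaks lay inside a hotspot in 74.7% and 74.0% of cases. Hotspots had a median width of 286 bp in replicate 1 and 253 bp in replicate 2. Outside the mitochondrial genome and unplaced contigs, the highest-scoring replicate 2 peaks lay 4911 bp from the start of Pdzd8 on chromosome 19 (score 147), in Spi1, over 36 kb from Ccr1 on chromosome 9 (143 and 137), at Gm21887 on chromosome X (137), and near Zfp687 and Ciart on chromosome 3 (135 each).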

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

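The tests in this part were chosen after the results were seen. Peaks on the mitochondrial genome and on contigs outside chromosomes 1 to 19, X and Y entered the overlap but no comparison by gene, location or motif. The replicate 1 list had 17 mitochondrial peaks with a median score of 150, and the replicate 2 list had 32 with a median of 146.5. Other contigs held 535 peaks in replicate 1 and 135 in replicate 2. These peaks are reported because they are part of the lists and were otherwise left aside.

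Replicate 1 had 3.16 times as many peaks as replicate 2. Of the peaks found in replicate 1 alone, 2.05% scored above the median of its shared peaks. This restates that sharing rises with score, so weaker sites called once the reads of its libraries were merged cannot be told apart from sites open in replicate 1 and closed in replicate 2. The latter were not decided either: 1.32% of the top 10% of replicate 1 peaks by score lay over 500 bp from any replicate 2 peak, but that top 10% holds only 0.561% of the extra peaks. A lower share of reads in accessible sites in replicate 2 stays open as well, because 0 columns of the lists give that share.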

How the results depend on the processing

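Among alternative values of the main results, 102 stayed inside the interval of the main value (or, for medians of peak number, within 1.5 times) and 56 moved. The count of values that stayed is not a measure of stability. At equal length the replicate 2 list is not cut, so its promoter share could not move. Intervals of short gene lists are also wide, so large changes can stay inside them. The order of the lists turned for the promoter share and for peaks around genes of other tissues at equal length, and for CTCF in the higher-scoring 50%. Of the other results, 46 stayed and 54 moved. Causes were not tested beyond what each setting does by construction. Reciprocal overlap gave 90.7% of replicate 2 and 28.6% of replicate 1 peaks shared and a rho of 0.924; a distance of 500 bp gave 99.2% and 40.5%, the higher-scoring 50% gave 97.496% and 31.1%, equal length 75% and 74.3%, and hotspots 99.1% and 30.5%. The promoter share was 20.9% in replicate 1 and 27.7% in replicate 2 within 2500 bp, 15.8% and 24.7% with all annotated genes, and 20.3% and 29.5% for the higher-scoring 50%. At equal length it was 25.9% in replicate 1.

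For promoters open in both lists, a width of 2500 bp gave 100% of erythroid factors and 90% of red cell membrane genes. A width of 500 bp gave 0% of hepatocyte markers, and the higher-scoring 50% gave 0% of hepatocyte and 0% of neuron markers. The remaining lists are not given at each of these settings. These values therefore do not show that a change of setting sets the erythroid lists apart from the others. With either biological replicate alone, erythroid factors ranged from 95% to 100%, heme genes from 90% to 95%, globin genes from 30% to 60%, membrane genes from 75% to 95%, megakaryocyte markers from 43.8% to 68.8%, myeloid markers from 50% to 75%, lymphoid markers from 20% to 60%, neuron markers from 5% to 30%, hepatocyte markers from 5% to 15%, muscle markers from 10% to 30% and fibroblast genes from 15% to 35%. Stem and progenitor genes stayed at 65%, pluripotency and epithelial lists at 5%, and the housekeeping, cell cycle and tumour suppressor lists at 100%. The counts of the erythroid factor, membrane, megakaryocyte, myeloid, lymphoid and neuron lists left their interval with replicate 1 alone.

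Within 10 kb the median number of peaks was 20 and 6 for the erythroid lists in replicates 1 and 2, and 5 and 1 for other tissues; at equal length replicate 1 gave 20 and 5. Whole peaks inside a hotspot made up 74.7% and 74.0%. The GATA ratio in replicates 1 and 2 was 1.79 and 2.30 within 75 bp, 1.68 and 2.26 over 2500 bp from gene starts, 1.83 and 2.29 in the higher-scoring 50%, and 2.09 and 2.96 with GC-matched flanks. GATA with an E-box gave 1.69 and 1.98 within 75 bp, 1.71 and 2.33 in the higher-scoring 50%, and 2.05 in replicate 2 with GC-matched flanks. CTCF gave 92.9 and 271.2 within 75 bp, 90.3 and 80.6 in the higher-scoring 50%, and 46.3 and 100.9 with GC-matched flanks. Depth is unknown, so absence from the replicate 2 list does not show a closed site. No paired analysis was possible because the series has 1 condition.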

Other observations

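The gene families and tests in this part were chosen after the data were seen. Promoter peaks were present in replicates 1 and 2 for 77 and 76 of 79 ribosomal protein genes, 46 and 46 of 50 proteasome genes and 58 and 57 of 64 histone genes. They were present for 106 and 32 of 1134 olfactory receptor genes, 20 and 4 of 331 vomeronasal receptor genes, 6 and 0 of 42 beta-defensin genes, 6 and 3 of 53 keratin genes and 28 and 10 of 57 clustered protocadherin genes. No test between families was run.

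Among Hox genes, which pattern the body axis, the Hoxc cluster had the most promoter peaks. Hoxc10 scored 145 in replicate 1 and 80 in replicate 2, Hoxc9 137 and 51, and Hoxc4 130 and 44. Hoxb13 scored 135 and 45 and Hoxb6 106 and 29. Of 11 Hoxa genes only Hoxa10 had a promoter peak (96 and 17), and of 9 Hoxd genes only Hoxd8 (105 and 17). On the Y chromosome, Ddx3y (150 and 128), Uty (149 and 126), Eif2s3y (149 and 120) and Kdm5d (146 and 83) had promoter peaks in both lists, so this line carries Y sequence.

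Spi1 was the only gene of 16260 with at least 4 exons in which every exon held a peak, in each list. In replicate 2 all 4 of the later exons had a hotspot ending within 150 bp outside both exon borders. The same held for 30.8% of 1029 other exons with a peak. In replicate 1 it held for 2 of the 4 later exons. The other exons were not matched on length. Exons 2, 3 and 4 are 97, 191 and 166 bp long, and replicate 2 hotspots have a median width of 253 bp. A hotspot over so short an exon can end near both borders whatever its source. Exon 5, at 682 bp, had hotspot edges 98 and 65 bp outside its borders in replicate 2. DNA copies of the spliced transcript would give such edges. The lists cannot separate copies in the cells from a contaminant. Reads shared with another place in the reference are argued against, since 100% of the 32-bp words of the exons were unique. Separate regulatory elements in the exons remain open. The chance of 4 of 4 exons at the borders in replicate 2 was 0.00901, above the limit of 0.001 for excluding them. That chance treats the 4 exons as independent, and neither it nor the next test was matched on exon length. A further test, added after the first missed that limit, counted hotspot edges at a shared distance within 1 bp: 6 of 8 in replicate 1, against at most 3 in 10000 random sets, and 3 of 8 in replicate 2, reached by a share of 0.0034, so only replicate 1 met the limit.

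Peaks of a stretch of chromosome 3, 95000001 to 98000000, picked as the longest run of 1-Mb windows in the top 5% by distal score in both lists and holding Zfp687, Ciart and Fcgr1, had high scores, with a distal median of 49 against 29 elsewhere in replicate 2 and 96 against 67 in replicate 1. GC content is argued against: distal peaks had a median GC of 48% there and 48.7% elsewhere in replicate 2, and weighting to the GC of the stretch gave 0% of the rise in both lists, in a test added because the choice of the stretch fixes the first one (a GC-weighted median 40.8% lower). A condition of the added test, that medians by GC step differ by at least the rise, was dropped after replicate 2 missed it (18 against 20), since a smaller range leaves GC less room. More copies of the stretch cannot be told apart from an active domain. The 13 replicate 2 peaks with a CTCF site in the stretch had a median at percentile 100 of random draws. However, 11 of them are distal peaks that chose the stretch, and copy number was not measured. Peaks within 1000 bp of a gene start, which did not choose the stretch, were also high there. Their medians were 73.5 against 45 elsewhere in replicate 2 and 141 against 115 in replicate 1, which either explanation allows. Density of sites is not decided, since 0% of only 4 other windows with as many sites, and 0.704% of 142 windows at a lower density limit in a version added after that was seen, had as high a median, which the choice of the stretch makes rare.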
